A study of Saccharomyces cerevisiae with 7 samples.

How the data were processed

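The data are 7 arrays with 2 channels, 1 per time point of a meiotic course of the Clb5 and Clb6 double mutant. Per the labels' protocols, cells were collected by filtration and frozen, total RNA was extracted with acid phenol, poly(A) RNA was isolated, and cDNA was coupled to Cy5; the Cy3 channel held a mix of mRNA from the time points. Per the series design in the labels, the authors divided the ratio of sample to mix by the same ratio at 0 h and took log2, so the deposited values are log2 ratios to 0 h, and a positive value means more mRNA than at 0 h. The scanner, the background correction, the filter on dim spots and any normalization within or between arrays are not given in the sources used here. No spot intensities were used here, so neither the signal above background behind a ratio nor a list matched on expression could be given.

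Libraries were grouped by the time in their titles. The library titled 8 h carries the source name of 6 h, and its time taken as 6 h and its omission were both tried as alternatives. The table has 1 row per open reading frame, 6141 in all, of which 5655 matched a locus tag in the RefSeq gene table of assembly R64 and 486 were kept under their systematic name; 5130 of the matched ones have a gene symbol. That table was used for names and for which genes neighbour each other. A value was missing for 331 to 516 open reading frames per library, and 303 had none in any library. Library medians lay between -0.01 and 0.09, and the SD of the log2 values went from 0.96 at 1 h to 1.65 in the library titled 8 h.

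Without replicates, genes at least 2-fold (1 log2 unit) from 0 h were counted per library with no test. The trend over time was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) as a slope per hour over the 7 libraries, on the 5349 genes with a value in each, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 0 h array is a constant per gene and does not enter the slope. The p-values measure the scatter of single successive samples around the line, with 5 residual degrees of freedom. A natural spline of time with 2 degrees of freedom (F test) was used beside the line and finds genes that go up and come down. "Rose" and "fell" in the text mean that the line passed the threshold, and "changed" that the spline did.

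Before the data were examined, 24 gene lists with 747 members were fixed, of which 738 are on the array. Each list's median per library was set against 10000 random lists of its size, and its trend was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry as alternatives. The genes named were fixed by a rule: CLB5 and CLB6, a set of key genes, the 12 highest and 12 lowest means among genes with the same sign in all 7 libraries, the 10 steepest slopes each way past the threshold, and in each list the 3 largest slopes and 2 largest means. RIM101, DUN1, MCD1, RAD61, CLN1, SIC1 and CSE4, and STE18, AXL1, MFA1, GPA1, FUS1, FUS3, FAR1, SST2, MFA2, MF(ALPHA)1, PFY1, TPM1, SPO71, SPO75 and SMA2, fall outside that rule and were chosen after their values were seen. The array has no probe row under the names of SAE3, HED1, SSP160, HUG1, NOP10, ATP18, TIM11, DDR2 and ARG5,6 as matched here.

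The alternatives were centring each library, bringing libraries to the same median absolute deviation, quantile normalization, the 1 h library as baseline, genes measured in all 7 libraries, a change held in neighbouring time points, the rank of the time points, 5, 6 and 8 h against 1, 2 and 3 h, robust eBayes, genes with 5 or more values, and leaving out each library. The limma steps were tested on simulated data for 5349 genes: a slope of 0.1 per h was recovered in 3% of changed genes, 0.3 in 61.2% and 0.6 in 95.5%, with 6 false calls among 112. The simulation had straight slopes, independent noise and 66 or 67 changed genes per slope size. The real course had curved profiles, dependent samples and many more calls, so these rates need not hold for it. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.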

Results

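Messenger RNA was measured over a meiotic time course in a budding yeast mutant that lacks Clb5 and Clb6, the B-type cyclins that partner the kinase Cdc28 at the start of S phase and are known to be needed for DNA replication before meiosis. The course held 7 libraries, 1 each at 1, 2, 3, 4, 5, 6 and 8 h, with no replicate at any time point. Each value was the log2 ratio of a gene's mRNA at that time to its mRNA at 0 h, with a pool of mRNA from the course as the common reference on every array. Of 6141 open reading frames, 5349 had a value in all 7 libraries, and between 5625 and 5810 had one in each library. The number of arrays, 1 per time point, limits the precision of every value. The labels of the last library conflict, since its title says 8 h and its source name 6 h, so it is called the library titled 8 h. No wild-type course was analysed here, so the values describe the mutant alone.

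The deleted genes were read first. CLB5 (YPR120C) had log2 ratios between -0.51 at 4 h and 1.40 at 1 h, and its slope over time was 0.05 ± 0.10 log2 units per h (SE, limma adjusted p = 0.714); by the spline of time it changed (limma adjusted p = 0.0496). CLB6 (YGR109C) rose, from -0.53 at 2 h to 1.27 in the library titled 8 h, with a slope of 0.28 ± 0.06 per h (limma adjusted p = 0.00526). A ratio to the same strain at 0 h carries no level, and it is not given which part of each gene its probe reads, so these values neither bear out nor contradict the deletions. By systematic number CLB6 lies beside CLB1 (YGR108W), looked up after the values were seen. CLB1 rose as well, from 1.07 at 1 h to 3.84 in the library titled 8 h. Whether the rise read for CLB6 is that of CLB6 itself is open.

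The first comparison asks how far the transcriptome of the mutant stood from 0 h at each time. Meiotic recombination genes, histone genes and genes of nitrogen-poor growth were above their 0 h level within the first hours, while ribosomal protein and glycolytic genes were far below it from 1 h on. HOP1, a protein of the meiotic chromosome axis, and ZIP1, which forms the transverse filaments of the synaptonemal complex, stood at 5.42 and 4.75 at 4 h. DMC1, the meiotic strand-exchange protein, stood at 5.14 and REC8, the meiotic cohesin subunit, at 5.56 in the same library. ENO1, an enolase of glycolysis, had the lowest mean of the genes measured throughout and reached -6.59 in the library titled 8 h. At 1 h, 682 genes were at least 2-fold higher than at 0 h and 693 at least 2-fold lower. These counts were 1024 and 915 at 4 h, and 1278 and 1155 in the library titled 8 h. A wider spread of the later libraries and larger counts past a fixed cut are nearly the same observation, and scaling that evens out the spread evens out the counts by construction. With libraries brought to the same spread they were 824 and 1033 at 1 h, 950 and 930 at 4 h and 996 and 824 in the library titled 8 h. After quantile normalization they were 984 and 904 at 1 h and 970 and 891 in the library titled 8 h. Over the whole course 210 of 5349 genes were at least 2-fold higher in all 7 libraries and 330 at least 2-fold lower in all 7, while 1874 reached 2-fold in none. With 1 library per time point these counts have no replicate check and no p-value. All 7 libraries share the 0 h array, so an error in it would move a gene alike at every time; against the 1 h library, 201 genes were at least 2-fold higher and 159 at least 2-fold lower at 2 h, where the counts against 0 h were 747 and 712.

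Genes that act early in meiosis were high from the start and highest at 4 h. The list of recombination and synapsis genes had a median log2 ratio of 1.98 at 1 h, 3.39 at 4 h and 1.96 in the library titled 8 h, above all 10000 random lists of its size in each library. Of its 29 members with a value throughout, 24 had their highest value at 4 h. SPO11, the protein that makes meiotic double-strand breaks, stood at 1.66 at 1 h, 3.01 at 4 h and 1.19 in the library titled 8 h. SPO13, which acts on sister kinetochores in meiosis I, stood at 3.56, 5.57 and 2.99 in those libraries, and MEK1, the meiotic checkpoint kinase, at 4.16, 5.35 and 3.40. MEI5, a partner of Dmc1, was among the 12 genes with the highest mean and lay between 4.29 and 6.44. A straight line fits such a course poorly: 1 member rose and 1 fell, the latter MND1 with a slope of -0.23 ± 0.08 per h (limma adjusted p = 0.0415, and 0.398 with a slope of -0.11 without the library titled 8 h), and the list as a whole had a camera adjusted p of 0.381, or an adjusted p of 0.966 with an estimated correlation. A spline of time with 2 degrees of freedom found that 26 of the 29 changed. The direction depended on the setting: the list's mean slope was -0.22 per h with libraries brought to the same spread (camera adjusted p = 6.51e-06), -0.35 after quantile normalization (2.23e-07), -0.16 without the 1 h library (0.00152) and 0.11 without the library titled 8 h (0.0382).

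**Figure D1:**
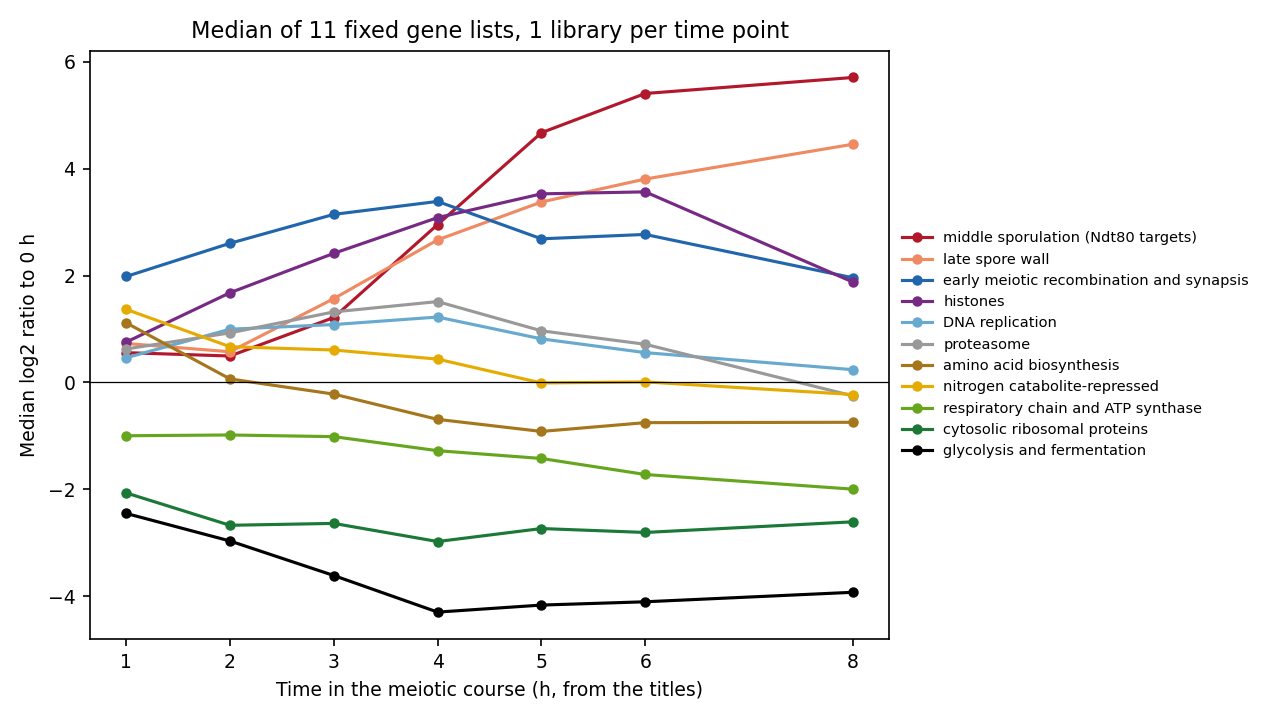
Median log2 ratio to 0 h (vertical axis, log2 units) against time in hours (horizontal axis) for 11 of the fixed gene lists; each point is the median over the members of a list in 1 library, and there are no replicates to give an error. Middle sporulation genes climb to a median of 5.71, early meiotic genes are highest at 4 h with 3.39, and glycolytic genes are lowest at 4 h with -4.30.

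The regulators of entry into meiosis and of its middle phase moved in different ways. NDT80, the transcription factor that switches on the middle sporulation genes, rose from -0.56 at 1 h to 6.18 at 6 h, with a slope of 1.05 ± 0.16 per h (limma adjusted p = 0.00197). IME1, the master activator of meiosis, fell over the course (slope -0.31 ± 0.09 per h, limma adjusted p = 0.0307, and 0.381 with a slope of -0.12 without the library titled 8 h), although it stood at 1.45 at 4 h before it reached -1.29 in the library titled 8 h. IME2, the meiotic kinase, lay between 3.48 and 5.88, and its slope did not pass the test (limma adjusted p = 0.205). By the spline of time IME2 changed (limma adjusted p = 0.0031). IDS2 rose and RIM101, a pH-response factor, fell, so that 2 of 14 regulators tested rose and 2 fell. The list had a camera adjusted p of 0.381, or an adjusted p of 0.825 with an estimated correlation; without the library titled 8 h its camera adjusted p was 0.0171.

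The second comparison asks which genes rose or fell along a straight line fitted from 1 h to the library titled 8 h. A gene can pass that test without a steady course. Sporulation genes led the rises, and genes of nitrogen-poor growth and amino acid synthesis were among the steepest falls. SPS2 and SPR2, both of the spore wall, rose to 10.55 and 10.16 in the library titled 8 h, with slopes of 1.61 ± 0.18 and 1.60 ± 0.15 per h. MEP2, an ammonium transporter, fell from 6.92 at 1 h to 2.12 with a slope of -0.76 ± 0.12 per h, and ARG1, an enzyme of arginine synthesis, fell from 2.27 to -2.30. Of 5349 genes tested with limma, 965 rose and 806 fell. The p-values measure the spread of successive samples of 1 course around a line, not the spread between cultures, and neighbouring samples are not independent. The count of genes that fell was 512 without the 2 h library. With the library titled 8 h taken as 6 h, 754 genes rose and 653 fell. Of the genes that changed by the spline, 1575 had a fitted end above the start and 1687 one below it. The F test finds any change over time, so that direction was not itself tested.

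Middle sporulation genes, the targets of Ndt80 that carry cells through the meiotic divisions and spore formation, rose with 1 exception. Of 42 members 41 rose and none fell, and their median went from 0.56 at 1 h to 2.95 at 4 h, 4.67 at 5 h and 5.71 in the library titled 8 h. The septin SPR3 rose with a slope of 1.51 ± 0.19 per h, the kinase SPS1 with 1.41 ± 0.18 and the kinase SMK1 with 0.98 ± 0.12. CDC5, the polo kinase needed to leave pachytene, rose from 1.57 at 1 h to 6.42, and the cyclins CLB1 and CLB3 rose to 3.84 and 4.08 in the library titled 8 h. The 1 member that did not pass was SPS4, with values between 0.24 and 0.93. The camera adjusted p of the list was 8.37e-22, and the adjusted p was 0.295 with an estimated correlation, where none of the 24 lists passed.

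Late spore wall genes also rose, 7 of 12 members with none falling. CDA1, a chitin deacetylase of the spore wall, reached 7.88 and LOH1 8.05 in the library titled 8 h. DIT1, of the dityrosine layer of the wall, stayed between 0.05 and 0.50 up to 6 h and stood at 3.01 in the library titled 8 h (limma adjusted p = 0.0433 for its slope, and 0.677 without that library). SPS100, a late marker of wall maturation, was below its 0 h level in all 7 libraries. The list median was 4.46 in the library titled 8 h, with a camera adjusted p of 0.000227 and an adjusted p of 0.183 with an estimated correlation.

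**Figure D2:**
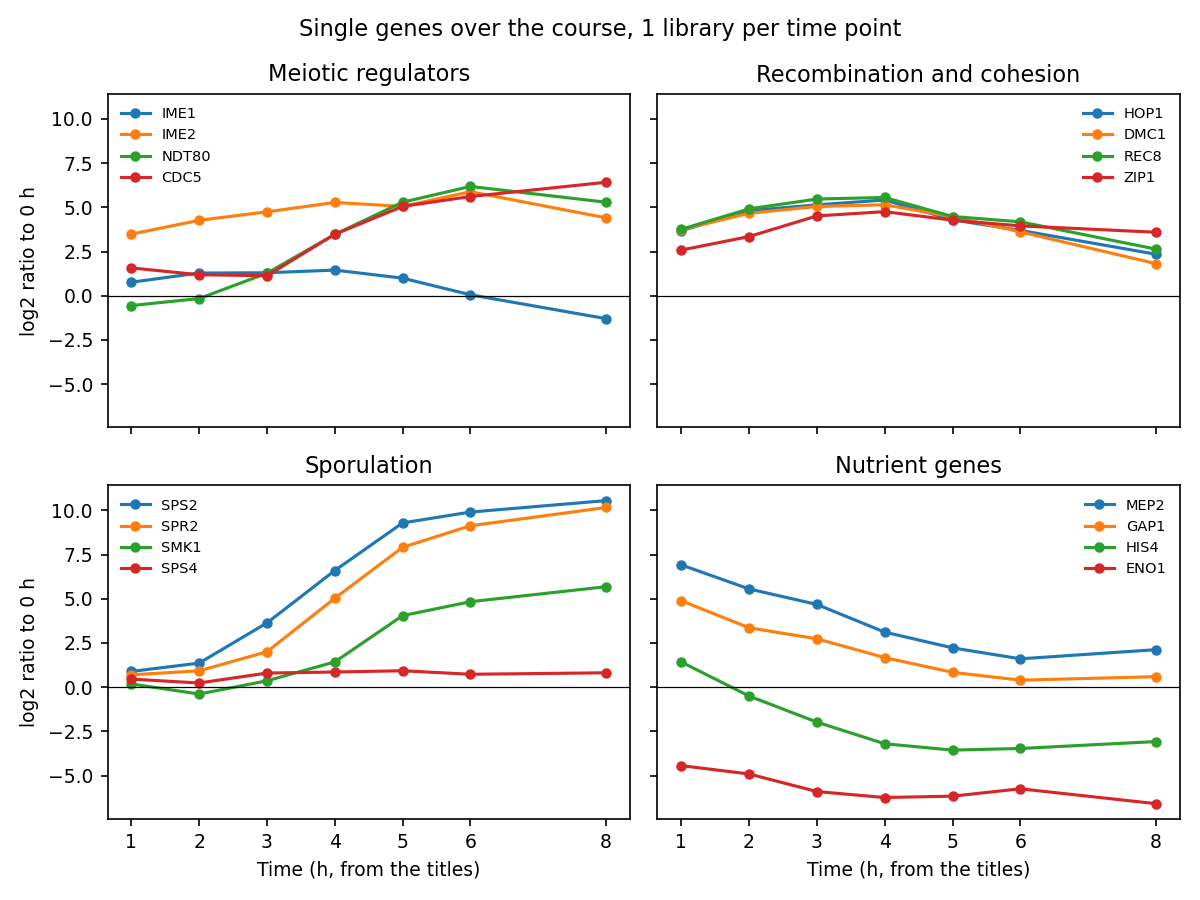
Log2 ratio to 0 h (vertical axes, log2 units) against time in hours (horizontal axes) for 16 genes in 4 panels; each point is 1 library, and there are no replicates to give an error. NDT80 and CDC5 climb after 3 h, HOP1, DMC1 and REC8 are highest at 4 h, SPS2 reaches 10.55 while SPS4 stays under 1, and ENO1 lies below 0 throughout.

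Genes of DNA replication were moderately high at 2 to 4 h. The list median was 0.46 at 1 h, 1.22 at 4 h and 0.24 in the library titled 8 h. POL1, the catalytic subunit of DNA polymerase alpha, stood at 1.76 at 3 h, and RNR1, the large subunit of ribonucleotide reductase, went from -0.05 at 1 h to 1.95 at 3 h and -0.53 in the library titled 8 h. The spline found that 30 of 47 members changed, RNR1 being in another list, while by the line 4 rose and 4 fell; the origin recognition genes ORC3 and ORC1 rose with slopes of 0.59 ± 0.08 and 0.51 ± 0.06 per h. Both lie beside a sporulation gene, looked up after the values were seen: ORC3 went up by 3.50 and SPO75 by 3.43 from 1 h to the library titled 8 h (correlation 0.975), and ORC1 by 3.14 and SMA2 by 5.73 (0.963), so whether these 2 rises are those of the replication genes themselves is open. The list had a camera adjusted p of 0.924, or an adjusted p of 0.966 with an estimated correlation; without the 1 h library its mean slope was -0.07 per h with a camera adjusted p of 0.0286. Among 19 genes of ribonucleotide reductase and the DNA damage response, DIN7 and LCD1, the latter the partner of the checkpoint kinase Mec1, rose and DUN1 fell. That list had a camera adjusted p of 0.967, or an adjusted p of 0.966 with an estimated correlation.

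Histone genes were high longer than the replication genes. The median of the 11 histone genes was 0.75 at 1 h, 3.08 at 4 h, 3.57 at 6 h and 1.88 in the library titled 8 h. HTB1, which codes for histone H2B, stood at 4.43 at 6 h and HTA1, which codes for H2A, at 4.04 at 5 h. The linker histone HHO1, the variant HTZ1 and the centromeric CSE4 rose along the line together with HTA2, 4 of 11, and the spline found that all 11 changed. The list rose with a mean slope of 0.21 per h and a camera adjusted p of 0.0122, and the adjusted p was 0.638 with an estimated correlation. That call was lost with libraries brought to the same spread (slope 0.10, camera adjusted p = 0.201), after quantile normalization (0.03, 0.314), without the 1 h library (0.09, 0.177) and with fry (adjusted p = 0.0744). The slope was larger without the library titled 8 h (0.49, camera adjusted p = 9.21e-08) and with that library taken as 6 h (0.35, 0.000453).

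Cohesion genes moved apart. PDS1, the securin, and SGO1, the shugoshin that protects centromeric cohesin, rose with slopes of 0.54 ± 0.08 and 0.54 ± 0.10 per h, that of SGO1 being 0.81 without the library titled 8 h. MCD1, the mitotic counterpart of REC8, fell and lay between -1.76 and -0.42, and RAD61 fell as well. The list of 12 had a camera adjusted p of 0.381, or an adjusted p of 0.825 with an estimated correlation. Of 20 mitotic cell cycle genes tested, 6 rose and 2 fell: CDH1, an activator of the anaphase-promoting complex, reached 2.38, NDD1 2.71 and the kinase SWE1 1.57 in the library titled 8 h, while the G1 cyclin CLN1 and the inhibitor SIC1 fell. This list had a camera adjusted p of 0.178, or an adjusted p of 0.638 with an estimated correlation.

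Genes of protein synthesis were far below their 0 h level throughout. The median of the cytosolic ribosomal proteins was -2.07 at 1 h and -2.98 at 4 h, and at least 122 members were 2-fold lower in each library. RPL2A reached -4.62 and RPS3 -4.42 at 4 h. RPL43B stood apart, at 1.76 at 4 h, before it reached -0.93. It lies beside IME1, a pair picked for its likeness after the values were seen. From 1 h to the library titled 8 h the change was -1.99 for RPL43B and -2.06 for IME1 (correlation 0.9725). Whether this course is that of RPL43B itself is open. Of 126 tested, 22 fell and none rose, with a camera adjusted p of 0.0181 and an adjusted p of 0.825 with an estimated correlation; the mean slope of -0.05 per h turned to 0.15 with libraries brought to the same spread, 0.04 after quantile normalization and 0.01 without the 1 h library, with camera adjusted p of 7.64e-10, 0.0490 and 0.866, and fry gave an adjusted p of 0.369. Without the library titled 8 h the slope was -0.11, and with it taken as 6 h -0.08. Ribosome biogenesis genes had medians between -1.30 and -0.88, with 5 of 57 rising, the helicase DBP3 among them, and 5 falling; the camera adjusted p was 0.967, and the adjusted p was 0.966 with an estimated correlation. The list passed upward with libraries brought to the same spread (mean slope 0.10 per h, camera adjusted p = 0.00128) and after quantile normalization (0.07, 0.00839).

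Glycolytic and fermentation genes were the lowest list, with a median of -2.45 at 1 h and -4.30 at 4 h. PGK1 reached -5.41 at 5 h, and TPI1 fell with a slope of -0.41 ± 0.07 per h. Of 17 members 8 fell and none rose, with a camera adjusted p of 0.000742 and an adjusted p of 0.638 with an estimated correlation; the mean slope of -0.20 per h turned to 0.05 with libraries brought to the same spread, and the call was also lost after quantile normalization (-0.07, camera adjusted p = 0.186) and with fry (adjusted p = 0.0744). Without the 1 h library the slope was -0.12 (camera adjusted p = 0.0412). Respiratory chain and ATP synthase genes fell from a median of -1.0 at 1 h to -2.0 in the library titled 8 h, 17 of 30 with none rising; QCR8 and ATP4 reached -2.95 and -3.03. Their camera adjusted p was 1.56e-05, and the adjusted p was 0.295 with an estimated correlation; with libraries brought to the same spread the mean slope went from -0.15 to -0.03 per h and the call was lost (camera adjusted p = 0.195). Of 17 tricarboxylic acid cycle genes 7 fell, CIT3, IDP1 and SDH3 most steeply, with a camera adjusted p of 0.0118, one of 0.0912 without the library titled 8 h, and an adjusted p of 0.295 with an estimated correlation. Of 19 genes of the glyoxylate cycle, gluconeogenesis and acetate use, 12 fell and none rose, with a camera adjusted p of 6.55e-06 and an adjusted p of 0.0766 with an estimated correlation. MLS1, malate synthase, fell from 0.73 to -2.67, and ACS1, acetyl-CoA synthetase, from 1.57 to -2.08, while ICL1, isocitrate lyase, stayed between -0.07 and 0.33.

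Genes repressed by good nitrogen sources were high at 1 h and fell from there. Their median was 1.37 at 1 h and -0.23 in the library titled 8 h, and 16 of 29 fell with none rising. The amino acid permease GAP1 fell from 4.89 to 0.59, while DAL80, a repressor of the same group, stayed between 2.88 and 3.93. The camera adjusted p was 1.79e-06, and the adjusted p was 0.183 with an estimated correlation. Amino acid biosynthesis genes had a median of 1.12 at 1 h and -0.75 in the library titled 8 h; 29 of 54 fell and 1 rose. HIS4 fell from 1.43 at 1 h to -3.07 and ARO8 from 2.09 to -2.14. The camera adjusted p was 8.41e-09, and the adjusted p was 0.638 with an estimated correlation. The mean slope of -0.25 per h was -0.15 without the 1 h library and -0.38 without the library titled 8 h.

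Proteasome genes were highest at 4 h, 27 of 32 of them, with a median of 0.62 at 1 h, 1.51 at 4 h and -0.25 in the library titled 8 h. The base subunit RPT4 stood at 2.15 at 4 h and -0.69 in the library titled 8 h. The spline found that 23 of 32 changed; by the line 1 fell, and the list had a camera adjusted p of 0.0222 and an adjusted p of 0.825 with an estimated correlation. The mean slope of -0.11 per h was -0.18 without the 1 h library and turned to 0.01 without the library titled 8 h, with a camera adjusted p of 0.781, and the call was also lost with that library taken as 6 h (0.223), with the rank of the time points (0.0681) and with fry (adjusted p = 0.369).

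Several single-gene calls were lost when 1 library was left out. Some lay close to the threshold, such as PGK1 (limma adjusted p = 0.0473), and others did not, such as LCD1 (0.00969) and DBP3 (0.00805). LCD1 lay between 0.87 and 1.64 up to 6 h and stood at 3.33 in the library titled 8 h. Leaving out a library also leaves 4 residual degrees of freedom in place of 5, so a lost call alone does not show that the library carried the trend. The calls of IME1, MND1, RPL43B, DIT1, ACT1, CAP1, CLB1, YCR013C, IDS2, LCD1, CDH1, NDD1, DBP3 and NEJ1 were lost without the library titled 8 h, where the slope of IME1 went from -0.31 to -0.12 and that of CLB1 from 0.59 to 0.62. Those of ENO1, PGK1, YCR013C, HTA2, ATG8, ACT1 and CAP1 were lost without 1 h, where the slope of PGK1 went from -0.21 to -0.10. Without 2 h those of IME1 (slope -0.32), MND1, RPL43B, DIT1, ACT1, CLB1, ENO1, PGK1, YCR013C, HTA2, NDD1 and ATG8 were lost. The same held without 3 h for IME1, MND1, RPL43B, DIT1, ACT1, CAP1, PGK1 and ATG8, without 4 h for DIT1 and ACT1, without 5 h for RPL43B, PGK1 and ATG8, and without 6 h for IME1, MND1, RPL43B, ACT1, CAP1, CLB1, PGK1, HTA2 and ATG8. These lists are not complete. Among all genes named by the rule, 13 calls were lost without 1 h, 17 without 2 h and 10 without 3 h. Without 4 h 3 were lost, without 5 h 4, without 6 h 12 and without the library titled 8 h 17.

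With limma's p-values adjusted over the list alone, 8 late spore wall genes rose, and 5 ribosomal protein, 8 tricarboxylic acid cycle, 19 respiratory, 14 glyoxylate cycle and 17 nitrogen genes fell. In amino acid biosynthesis 2 rose and 39 fell, in DNA replication 3 rose and 2 fell, in cohesion 2 rose and 3 fell, and in ribosome biogenesis 4 rose and 3 fell. In trehalose and glycogen 1 rose and 6 fell, and no early meiotic or proteasome gene passed. The other lists had the same counts as before.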

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

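All alternatives were fixed before the data were examined; choosing the first probe of a gene could not change anything, since each open reading frame has 1 row. No paired analysis was possible because each time point has 1 library and no replicate numbers. Against the 1 h library the counts of genes at least 2-fold higher and lower were 201 and 159 at 2 h, 311 and 351 at 3 h, 527 and 548 at 4 h, and 662 and 688 at 5 h, the number of list medians of 1 or more was 15 in 6 libraries in place of 38 in the same 6 (41 in all 7), and the median of early meiotic genes in the library titled 8 h was -0.41; a baseline already 1 h into the course differs by construction. The contrast of 5, 6 and 8 h with 1, 2 and 3 h called 624 genes higher and 440 lower, on 6 libraries in place of 7. The spline is by construction a wider test. Of the genes that changed by it, 1575 had a fitted end above the start and 1687 one below it, a direction not tested. With an estimated correlation 0 lists rose and 0 fell, in place of 3 and 8. Leaving out each library gave 710 to 1134 genes that rose, 512 (without 2 h) to 982 that fell, 2 to 5 (without the library titled 8 h) lists that rose and 7 to 9 that fell. In these fits the list slope ran from -0.16 (without 1 h) to 0.11 (without the library titled 8 h) for early meiotic genes, from -0.18 to 0.013 (the same libraries) for the proteasome, and from -0.11 (without the library titled 8 h) to 0.0073 (without 1 h) for ribosomal proteins. With libraries at the same median absolute deviation, slopes turned to 0.048 for glycolysis, 0.15 for ribosomal proteins, 0.17 for ENO1, 0.16 for PGK1, 0.14 for YCR013C, 0.0011 for ENO2, 0.0090 for SDH1 and -0.024 for ATG8. After quantile normalization they turned to 0.041 for ribosomal proteins, -0.37 for IME2, -0.073 for YKR005C, -0.54 for RNP1, -0.085 for YGR226C, -0.48 for MEI5, 0.00086 for PGK1, 0.041 for YCR013C, -0.38 for SLZ1, -0.013 for SWI4, -0.25 for ATG8, -0.0093 for ATG4 and -0.095 for NEJ1. The end-to-end change of the spline was -0.013 for RNP1 and -0.0017 for HTB2. Both scalings shrink the wider later libraries; apart from that the cause was not tested. A further 25 list slopes and 73 slopes of named genes changed sign across settings without passing the threshold in either. No intensities were used, so what signal over background limits is unknown.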

Other observations

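Autophagy genes went both ways: ATG8, the membrane-conjugated marker of autophagosomes, rose from 2.60 at 1 h to 4.39 at 6 h and the protease ATG4 from 1.21 to 2.77, while ATG19, a cargo receptor of the vacuole-targeting pathway, fell from 1.21 to -1.15. Of 17 members 3 rose and 3 fell (camera adjusted p = 0.967, and adjusted p = 0.966 with an estimated correlation), but the slopes of ATG8 and ATG4 turned after quantile normalization, to -0.25 and -0.0093 per h. Of 11 actin and tubulin genes tested, 1 rose and 4 fell. The alpha-tubulin TUB3 rose to 2.12 at 6 h, the spline found that TUB1 and TUB2 changed, with values of 3.38 and 3.43 at 6 h, and ACT1, CAP1, PFY1 and the tropomyosin TPM1 fell. That list had a camera adjusted p of 0.596, or an adjusted p of 0.825 with an estimated correlation.

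Of 15 trehalose and glycogen genes 5 fell and 1 rose; TPS2, trehalose phosphatase, fell from 0.54 to -1.72 and GSY2, glycogen synthase, from -0.17 to -1.94 (camera adjusted p = 0.0784, and adjusted p = 0.482 with an estimated correlation; 6 other settings passed downward, with adjusted p from 0.0125 to 0.0454 and of 0.0171 without the library titled 8 h). SGA1, the sporulation glucoamylase that breaks down glycogen, rose from 1.32 at 1 h to 8.85 in the library titled 8 h. Of 27 heat shock and stress genes 5 rose and 7 fell: the small heat shock gene HSP26 rose from -1.34 to 0.59, HOR7 fell from 0.80 to -2.77, and HSP12 had values between -0.50 and 1.85 (camera adjusted p = 0.381, and adjusted p = 0.825 with an estimated correlation). The list of the 2 deleted cyclins had a camera adjusted p of 0.340, or an adjusted p of 0.715 with an estimated correlation.

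All tests below were chosen after the results they bear on had been seen, and those on divergent neighbours, unmatched reading frames and haploid genes were revised after their outcome was known. Of 100 orders of the 7 time points, the real one included, only the real order gave as many as 1771 genes with a trend. The highest other gave 1232. Shuffling breaks the likeness of neighbouring samples that any smooth course has, so this count cannot decide whether the trends arose by chance. For 5, 6 and 8 h against 1, 2 and 3 h the real split gave 1064 genes and the highest other 0; 1 of 10 splits was as large as the real one, and 10 splits are too few for a share under 0.05.

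Neighbouring genes were only slightly more alike than random pairs, with a median correlation of 0.082 over the 7 time points in 4106 pairs; RPL43B at 1.76 and IME1 at 1.45 at 4 h, and YCR013C at -4.49 and PGK1 at -5.32, are pairs picked for their likeness. Overlapping gene models argue for part of it, with a median correlation over the 7 time points of 0.479 in 52 pairs, but the 4054 pairs without overlap had a median of 0.0689, above the highest of 1000 random gene orders, 0.05, so overlap is not the whole cause (genes are not independent replicates). Open reading frames absent from RefSeq are not in these pairs, and a separate comparison took their neighbours by systematic number. There they correlated with the better of 2 neighbours at a median of 0.718 and matched ones at 0.476. The difference of 0.243 lay outside the 95% range of relabelling from -0.0955 to 0.0851. For these reading frames, but not for the 4106 pairs, a candidate explanation is that their probes read the transcript beside them. A promoter shared by divergent neighbours stays open, since their median exceeded that of convergent ones by 0.0966 with a one-sided permutation p of 0.0636. No biological explanation named by the design was tested.

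Histone transcripts were high late in a mutant without the cyclins of S phase. HHO1, HTZ1 and CSE4, which have no near-identical copy in the list, had a median of 1.81 at 6 h, although CSE4 alone was at 1.04. For these genes that argues against signal shared between near-identical gene copies. Their values cannot show whether the histone genes with such copies share signal, so for those it stays open. The same timing as the replication genes is argued against too: all 11 histone genes were highest after 4 h, while 34 of 47 replication genes were highest by 4 h. What holds histone transcripts high, and whether a wild-type course would differ, was not tested.

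Of 16 haploid and mating-type genes tested, normally off in diploid cells, 6 rose, none fell and 10 did not pass, and the list as a whole passed with fry alone (camera adjusted p = 0.196, adjusted p = 0.638 with an estimated correlation and fry adjusted p = 0.0290), among them STE4, STE5 and STE18 of the pheromone pathway, MFA1, AXL1 and the end-joining factor NEJ1. Haploid cells in the culture cannot be told apart from other explanations, since the change from 1 h to 8 h over all 16 had a median of 0.46 and an SD of 1.21, and members parted: MFA1 went up by 1.44, MFA2 and MF(ALPHA)1 had differences of -0.55 and 0.52, and GPA1 one of -0.93. Signal from a strongly rising neighbour may account for STE5, whose neighbour, the sporulation gene SPO71, went up by 3.59 against 2.86 for STE5; among all genes that rose, 121 of 841 (14.4%) had such a neighbour, so 1 of these 6 is close to that share. The other 5 that rose had no measured neighbour that rose more with a correlation of 0.8 or above. That rule misses a neighbour that rose slightly less or was not measured. Signal from a neighbour therefore stays open for these 5 as well. The NEJ1 slope turned to -0.09 after quantile normalization, no intensities show whether these genes are near background, and no biological explanation was tested.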
